A study of Mus musculus with 16 samples.

How the data were processed

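Poly(A) RNA of hepatocytes and of LSEC was sequenced after 70% partial hepatectomy in KO and FLOX mice, with 4 libraries in each of the 4 groups. Per the labels' protocols, hepatocytes were obtained by collagenase perfusion and differential centrifugation, and LSEC with magnetic beads against CD146. The groups were taken from the sample titles. The time after surgery was not given in the sources used here.

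HISAT2 2.2.1 and RSEM 1.3.3 are named in the submitters' processing notes, and the genome build and annotation were not given in the sources used here. The values in the deposited library files were FPKM, fragments scaled to gene length and library size, of 16248 genes. The unit was read from the values: the sums differ between libraries, while the sums of value times gene length are nearly equal. The authors' deposited table of LSEC also gave log2 fold changes and p-values with FDR for KO against FLOX, whose test program was not given in the sources used here. The FPKM in that table were identical to the library values for the shared genes. Gene symbols came from the authors' files for 14780 genes and from the reference annotation for 1256, and 212 had none. Of all gene identifiers 272 were absent from the reference annotation, so no coordinates are given.

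FPKM hold no counts, so the count-based tests fixed beforehand were replaced by the fallback fixed with them: limma with an intensity trend on log2(FPKM + 1), in R 4.3.3 with limma 3.58.1. Log2 fold changes are on that scale, which understates the change of genes with low values, and values printed as N-fold are ratios of the mean scaled FPKM of the groups. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9. Within the libraries of each comparison FPKM were scaled by a trimmed mean of log ratios (30% of ratios and 5% of mean levels trimmed, genes above 0.1 FPKM, unweighted). Genes with a scaled FPKM of at least 0.5 in at least 4 libraries were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The printed levels are scaled FPKM, except where deposited values are named, and the mitochondrial shares are percents of the deposited FPKM sums.

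The comparisons were KO against FLOX within LSEC and within hepatocytes (8 libraries each), the difference of these effects over 16 libraries, and LSEC against hepatocytes in FLOX mice. Single values were compared by exact two-sided permutation over the 70 assignments of 4 against 4 libraries, whose smallest possible p is 0.0286. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The lists covered endothelial, hepatocyte, macrophage, lymphocyte, neutrophil, stellate, bile duct and blood cells, cell cycle, Wnt, Notch, BMP, flow response, zonation, bile acid, lipid, clock, sex, interferon, inflammation, p53 and stress genes. The comparisons, tests, lists and naming rule were fixed before the data were examined. Lists of pancreatic, mitochondrially encoded and Y-linked genes were added afterwards, and islet hormone genes were not analysed here.

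The naming rule took Piezo1, Atf2, Id1 and Wnt2, the 8 largest rises and 8 largest falls among called genes with no overlap between KO and FLOX, and the members with the smallest p of each passing list. A mean scaled FPKM of at least 2 stood in for the fixed minimum of 50 counts, and 2 members per list were named where the rule allowed 3. For LSEC against hepatocytes it took the 5 members with the highest levels of 4 cell type lists. Some genes taken by the rule are not reported here.

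Replicates of a group correlated at 0.947 to 0.976 across genes, and no pair was identical. Depth is known only as an estimate from the steps between low FPKM values, so no counting intervals are given. Gene tests were tested on simulated FPKM with known changes. Of genes changed 1.5-fold, 2-fold and 4-fold, the LSEC comparison recovered 47.8%, 67.2% and 89.4%, with 11 false among 147 calls. The hepatocyte comparison recovered 38.8%, 65.7% and 93.9%, with 7 false among 139 calls. The interaction recovered 17.9%, 44.8% and 83.3%, with 1 false among 98, and the cell type comparison 28.4%, 55.2% and 95.5%, with 4 false among 123. A list raised 1.5-fold was called in both genotype comparisons, with no other list called. The simulated noise was independent between genes, so false list calls from correlated genes could not appear in it. In each comparison 67, 67 and 66 genes were changed, of 14854 tested for LSEC. In the real LSEC data 4220 of 14660 genes were called, so scaling under so many changes was not tested by the simulation. Recovery was not broken down by expression level, so it may not hold for genes with low FPKM.

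The alternatives were other scalings (relative log expression, upper quartile, and the FPKM as deposited), library quality weights in place of count weights, other filters and pseudocounts, stricter thresholds, the replicate number as a block, 1 fit over 16 libraries, the list of the other cell type as a covariate, and leaving out each library. The quality weights, scalings and filters planned for counts were applied to FPKM.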

Results

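Gene expression was measured by poly(A) RNA sequencing in 2 cell fractions of the mouse liver after 70% partial hepatectomy, an operation that removes most of the liver and sets off its regrowth. The fractions were hepatocytes, the parenchymal cells of the liver, and liver sinusoidal endothelial cells (LSEC), the fenestrated endothelium of the hepatic capillaries, taken with magnetic beads against the endothelial surface protein CD146. Each fraction came from mice that the labels give as lacking the mechanically gated cation channel Piezo1 in endothelial cells (KO) and from FLOX controls. The 4 groups of 4 libraries made 16 in all, and the values were FPKM of 16248 genes. The FPKM sum per library was 734321 ± 3607 in KO LSEC, 574500 ± 5703 in FLOX LSEC, 774380 ± 3668 in KO hepatocytes and 827393 ± 25830 in FLOX hepatocytes (SD, n = 4 each). Read counts were not used here. Steps between low FPKM values placed the depth of 12 of the libraries at about 13700000 to 23500000 fragments, and the steps were not resolved in the others. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Transcripts of both sexes were found in every library, so a library may also hold RNA of several animals. Among genes at 100 FPKM or more, the median coefficient of variation within a group was 6.14% to 10.2%.

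The fractions were first compared in FLOX mice, to show what each one contained. All 22 tested general endothelial genes were higher in LSEC, with a median ratio of 5.50. Endoglin (Eng), a co-receptor of the BMP pathway, stood at 757 ± 19.8 FPKM in LSEC and 118 ± 4.23 in hepatocytes. The VEGF receptor gene Kdr stood at 562 ± 2.96 and 85.4 ± 2.31, Egfl7 at 819 ± 30.4 and 153 ± 16.5, Ptprb at 399 ± 15.8 and 72.3 ± 2.98, and the adhesion molecule gene Pecam1 at 349 ± 17.7 and 71.1 ± 12.9 (SD, n = 4). Of 22 LSEC identity genes, 21 were higher in LSEC. They included the lectin gene Clec4g at 2712 ± 119 against 538 ± 56.1 FPKM, the Fc receptor gene Fcgr2b at 1001 ± 54.4 against 171 ± 26.9, the scavenger receptor gene Stab1 at 826 ± 32.2 against 103 ± 6.998 and Ehd3 at 744 ± 10.2 against 131 ± 5.30. The exception was Ctsl, which encodes the lysosomal protease cathepsin L, with a log2 difference of -0.31 that became 0.17 without library scaling and did not then pass the test (limma adjusted p = 0.0715, range over the scalings 0.00424 to 0.312).

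All 25 hepatocyte genes were higher in the hepatocyte fraction, with a median ratio of 62.9. Albumin (Alb) stood at 26795 ± 1278 FPKM in hepatocytes and 392 ± 27.6 in LSEC, transferrin (Trf) at 9942 ± 797 and 220.5 ± 35.4, Ahsg at 9591 ± 653 and 155 ± 14.1, the apolipoprotein gene Apoa1 at 6877 ± 903 and 91.9 ± 11.7, and the fibrinogen gene Fgg at 6788 ± 259.7 and 78.9 ± 11.1 (SD, n = 4). The 17 genes of Kupffer cells and macrophages were also all higher in the hepatocyte fraction, with Cd5l at 807 ± 97.4 against 154 ± 5.60, Marco at 748 ± 32.2 against 159.9 ± 14.9, Clec4f at 703 ± 80.6 against 165 ± 16.1, C1qc at 471 ± 55.4 against 114 ± 3.17 and C1qa at 466 ± 61.1 against 145 ± 9.04 FPKM. General endothelial genes reached a median of 18.2% of their LSEC level in the hepatocyte fraction, and hepatocyte genes 1.59% of their hepatocyte level in LSEC. Over all genes, 10188 of 14758 differed by limma (Benjamini-Hochberg adjusted p under 0.05), 4977 higher in LSEC and 5211 higher in hepatocytes, and 5627 of them by a log2 difference of at least 1. On the FPKM as deposited, whose median log2 difference between the fractions was 0.40, the split was 7088 against 3740.

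The targeted gene and the other 3 genes named in the series title were examined before all others. Piezo1 (ENSMUSG00000014444) stood at 47.4 ± 5.08 against 57.4 ± 6.40 FPKM in KO and FLOX LSEC (SD, n = 4), a log2 fold change of -0.27 ± 0.11 (SE) that did not pass the test (limma adjusted p = 0.0917; exact two-sided permutation p = 0.0857). On the FPKM as deposited the log2 fold change was -0.53 and passed (limma adjusted p = 0.00442, range over the alternatives 0.00442 to 0.983), with every KO library below every FLOX library. In hepatocytes Piezo1 stood at 6.06 ± 1.17 against 8.88 ± 0.983 FPKM (log2 fold change -0.49 ± 0.14, limma adjusted p = 0.0307; exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow). That call was lost when any of KO replicates 1, 2 and 4 or FLOX replicates 2 and 4 was left out (limma adjusted p = 0.0716, 0.0783, 0.0714, 0.0807 and 0.0712 in that order). The range over all alternatives was 0.00577 to 0.831. FPKM of a whole gene do not separate the deleted exons from the rest, so a transcript that keeps the other exons would still be counted, and these values check the deletion only in part. Relative to the mean of the general endothelial list, a measure chosen after the results were seen, Piezo1 was not lower in KO: it differed by 0.18 in LSEC (exact permutation p = 0.171), where 17 of 22 list members had lower log2 fold changes, and by 0.27 in hepatocytes (exact permutation p = 0.143), where 20 of 22 did (adjusted p = 0.206 each).

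**Figure D1:**
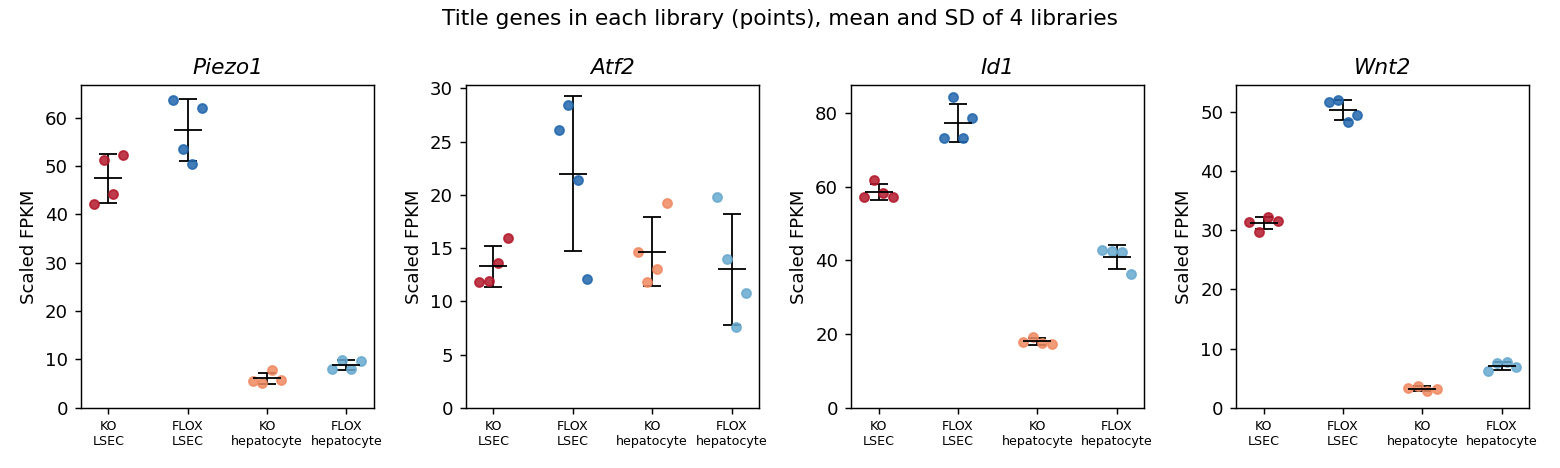
Scaled FPKM (vertical axes, from 0) of Piezo1, Atf2, Id1 and Wnt2 in the KO and FLOX libraries (points) of LSEC and hepatocytes, with bars for the mean and SD of 4 libraries. Wnt2 and Id1 lie lower in every KO library than in any FLOX library of the same cell type.

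Wnt2 (ENSMUSG00000010797), a secreted Wnt ligand of LSEC, fell in both fractions of KO mice. It stood at 31.2 ± 1.04 against 50.4 ± 1.71 FPKM in LSEC (log2 fold change -0.67 ± 0.062, limma adjusted p = 9.68e-05) and at 3.25 ± 0.359 against 7.09 ± 0.719 in hepatocytes (-0.93 ± 0.11, adjusted p = 0.000634). Id1 (ENSMUSG00000042745), an inhibitor of basic helix-loop-helix transcription factors, fell to 58.6 ± 2.24 against 77.3 ± 5.24 FPKM in LSEC (-0.39 ± 0.067, adjusted p = 0.00278) and to 17.997 ± 0.834 against 40.99 ± 3.19 in hepatocytes (-1.14 ± 0.080, adjusted p = 3.00e-05). The exact permutation p was 0.0286 in each of these 4 comparisons. Atf2 (ENSMUSG00000027104), a transcription factor of the CREB family, stood at 13.3 ± 1.93 against 22.01 ± 7.24 FPKM in LSEC (adjusted p = 0.0900), and without FLOX replicate 4 its log2 fold change of -0.89 passed (limma adjusted p = 0.00412, range over the alternatives 0.00412 to 0.983). In hepatocytes it stood at 14.7 ± 3.24 against 13.02 ± 5.22 FPKM (adjusted p = 0.607). General endothelial genes were lower in KO libraries at the same time, with a median log2 fold change of -0.45 in LSEC and -0.76 in hepatocytes. Adjusted over the list alone, these 4 genes all fell in LSEC, and Piezo1, Id1 and Wnt2 in hepatocytes. In the authors' deposited table of LSEC, the log2 fold changes were -0.31 for Piezo1 (FDR 0.00241), -0.42 for Atf2 (FDR 0.0202), -0.48 for Id1 (FDR 8.56e-08) and -0.75 for Wnt2 (FDR 2.66e-24).

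In LSEC, KO libraries held more transcripts of blood cells, macrophages and hepatocytes and fewer endothelial and mitotic transcripts than FLOX libraries. Of the genes named by a fixed rule, the globin genes, near-identical copies of one another within each family, showed the largest rises on the log2(FPKM + 1) scale: Hbb-bs reached 3845 ± 508 FPKM in KO against 47.8 ± 5.40 in FLOX, Hbb-bt 447 ± 14.8 against 4.69 ± 1.90, Hba-a2 5040.0 ± 507 against 66.6 ± 14.8 and Hba-a1 2081 ± 251 against 36.2 ± 7.97 (SD, n = 4). The heme synthesis gene Alas2 rose 32.4-fold, the immunoglobulin gene segment Igkv6-23 33.7-fold and the major urinary protein gene Mup9, whose family members are close copies, from 0.326 ± 0.398 to 46.97 ± 26.97 FPKM. The mitochondrially encoded mt-Nd6 rose 21.8-fold, and 12 of the 13 protein genes of the mitochondrial genome rose, a list added after the data were seen. The other member, mt-Co2, had a log2 fold change of 4.18 with a wide spread and did not pass (limma adjusted p = 0.0668). The kit was not stated to mark strand, so mt-Nd6, which lies on the opposite strand to the other protein genes, is uncertain. Mitochondrially encoded genes held 28.3% ± 0.501 of the FPKM sum in KO LSEC and 4.51% ± 0.226 in FLOX LSEC (SD, n = 4; exact permutation p = 0.0286).

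The largest falls in KO LSEC were those of Zfp46 (20.6 ± 3.89 against 90.3 ± 1.79 FPKM), Lrat (5.48 ± 0.244 against 22.2 ± 1.15), Get1 (2.14 ± 1.19 against 10.03 ± 4.97), Immp2l (0.540 ± 0.305 against 4.57 ± 2.82), Trbv14 (1.54 ± 1.16 against 6.85 ± 2.15), the imprinted gene Mest (9.84 ± 4.12 against 34.5 ± 11.5), Zfp354a (0.808 ± 0.843 against 4.70 ± 2.18) and Slc26a10 (51.5 ± 4.61 against 168 ± 5.58; SD, n = 4). Lrat encodes the retinol-esterifying enzyme of stellate cells, and Trbv14 is a T cell receptor gene segment. Their log2 fold changes ran from -2.10 for Zfp46 to -1.69 for Slc26a10, with limma adjusted p from 1.83e-06 to 0.0143. With a pseudocount of 0.1 the call on Trbv14 was lost (limma adjusted p = 0.0672, range over the alternatives 0.00192 to 0.983).

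All 17 tested genes of Kupffer cells and macrophages rose in KO LSEC, with a median log2 fold change of 1.61 (camera adjusted p = 1.64e-18). Cd5l, a secreted macrophage protein, stood at 547 ± 9.82 against 166 ± 6.18 FPKM and the complement gene C1qc at 402 ± 14.1 against 123 ± 3.30. Of 10 red cell and platelet genes 9 rose (camera adjusted p = 2.20e-10). Their median log2 fold change was 3.33. It reached up to 5.09 when KO replicate 1, 2, 3 or 4 was left out and ran from 1.502 to 5.09 over all alternatives. Of 17 lymphocyte genes 14 rose, among them the immunoglobulin gene Ighm (4.65-fold) and the granzyme gene Gzmb (1.88-fold; camera adjusted p = 9.57e-10). Neutrophil genes rose in 8 of 12 cases, led by the granule genes Ngp (188 ± 9.24 against 20.7 ± 1.05 FPKM) and Camp (4.25 ± 0.652 against 1.24 ± 0.350; camera adjusted p = 0.000142). All 21 acute phase genes rose, with a median log2 fold change of 1.94 (camera adjusted p = 4.84e-20). The siderophore-binding gene Lcn2 stood at 526 ± 40.8 against 90.8 ± 3.96 FPKM and the serum amyloid gene Saa3, one of a family of similar copies, at 563 ± 34.5 against 135 ± 6.01. Of 25 hepatocyte genes 18 rose and 1 fell (camera adjusted p = 2.17e-10; adjusted p = 0.0659 with an estimated correlation). The fibrinogen genes Fga and Fgg rose 4.60-fold and 4.08-fold, whereas Cps1, the first enzyme of the urea cycle, fell from 11.04 ± 1.09 to 3.84 ± 0.301 FPKM.

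Sterol and fatty acid synthesis genes rose in 14 of 20 cases and 1 fell (camera adjusted p = 9.29e-07), with Insig1, a regulator of sterol synthesis, up 2.05-fold. Fatty acid oxidation genes rose in 8 of 18 cases with none falling, including Angptl4 (5.18-fold), an inhibitor of lipoprotein lipase, and the peroxisomal enzyme gene Ehhadh (2.30-fold; camera adjusted p = 0.00362). Interferon response genes rose in 11 of 22 cases, as Ifit1 (1.86-fold) and Oas2 (1.83-fold), and 1 fell (camera adjusted p = 0.000262). NF-kB targets, chemokines and adhesion molecules rose in 14 of 22 cases and fell in 4 (camera adjusted p = 0.000112; adjusted p = 0.0913 with an estimated correlation). The chemokine gene Ccl3 rose 2.63-fold and P-selectin, Selp, 2.95-fold. Periportal genes rose in 5 of 17 cases, with Pigr, the transporter of IgA, up 3.45-fold, and Cps1 fell (camera adjusted p = 0.0241; adjusted p = 0.140 with an estimated correlation). Median log2 fold changes were 0.796 for lipid synthesis, 0.416 for fatty acid oxidation and 0.409 for periportal genes. The hepatocyte list had a median of 1.07 in the same libraries. In FLOX mice the lipid synthesis, fatty acid oxidation and periportal lists were lower in LSEC than in hepatocytes. More hepatocyte RNA in KO LSEC was therefore not separated from changes of these lists. Among genes known to respond to flow or stretch, 10 of 22 rose and 4 fell (camera adjusted p = 0.0438; adjusted p = 0.250 with an estimated correlation). The heme oxygenase gene Hmox1 rose 3.25-fold and Ankrd1 3.96-fold. Hmox1 rose about as much as the Kupffer cell list (log2 fold change 1.68 against a median of 1.61), and macrophage RNA was not separated for it. The median of the flow-response list was 0.17 after scaling and -0.082 on the FPKM as deposited, where the list did not pass (camera adjusted p = 0.144). Over the alternatives the adjusted p ran from 1.90e-05 by fry, which tests against no change rather than against other genes, to 0.301 by camera.

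Mitotic genes fell in 19 of 28 cases in KO LSEC and none rose (camera adjusted p = 7.17e-09). Top2a, the DNA topoisomerase of dividing cells, stood at 5.55 ± 0.767 against 15.2 ± 2.55 FPKM and the anaphase activator gene Cdc20 at 3.94 ± 0.480 against 8.85 ± 0.0956 (SD, n = 4). DNA replication genes fell in 15 of 30 cases and none rose, with Mcm5 of the replicative helicase at 10.4 ± 0.780 against 21.3 ± 1.51 and Dtl at 0.627 ± 0.106 against 2.84 ± 0.362 FPKM (camera adjusted p = 2.53e-07). Of 22 LSEC identity genes 16 fell and 1 rose (camera adjusted p = 9.07e-10), with Clec4g at 1729 ± 13.97 against 2931 ± 123 and Ehd3 at 502 ± 16.8 against 804 ± 16.8 FPKM. General endothelial genes fell in 16 of 22 cases and none rose (camera adjusted p = 1.06e-08). Clec14a stood at 48.4 ± 2.06 against 96.7 ± 2.88 and the endothelial transcription factor gene Sox18 at 21.7 ± 2.09 against 55.9 ± 4.12 FPKM. BMP and ID pathway genes fell in 10 of 19 cases and 1 rose (camera adjusted p = 0.000328; adjusted p = 0.0740 with an estimated correlation), among them the ligand gene Gdf2 (25.8 ± 2.68 against 55.2 ± 4.52 FPKM) and the inhibitory Smad6 (53.8 ± 3.78 against 89.9 ± 2.53). The median log2 fold change was -0.39 for BMP and ID genes and -0.45 for general endothelial genes. A lower share of endothelial RNA was not separated from a change of the BMP and ID list. Unfolded protein and stress response genes fell in 6 of 18 cases, with the endoplasmic reticulum genes Pdia4 and Sdf2l1 down 1.76-fold and 1.90-fold, and rose in 4 (camera adjusted p = 0.0462; adjusted p = 0.241 with an estimated correlation). Leaving out single libraries ended the calls on the flow-response list (without KO replicate 2 or 3 or FLOX replicate 2, camera adjusted p = 0.0524, 0.0501 and 0.0653, list median 0.16, 0.098 and 0.087) and on the stress-response list (without KO replicate 1 or 2 or FLOX replicate 3, 0.0670, 0.0829 and 0.0980, range over the alternatives 0.000119 by fry to 0.241 by camera).

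**Figure D2:**
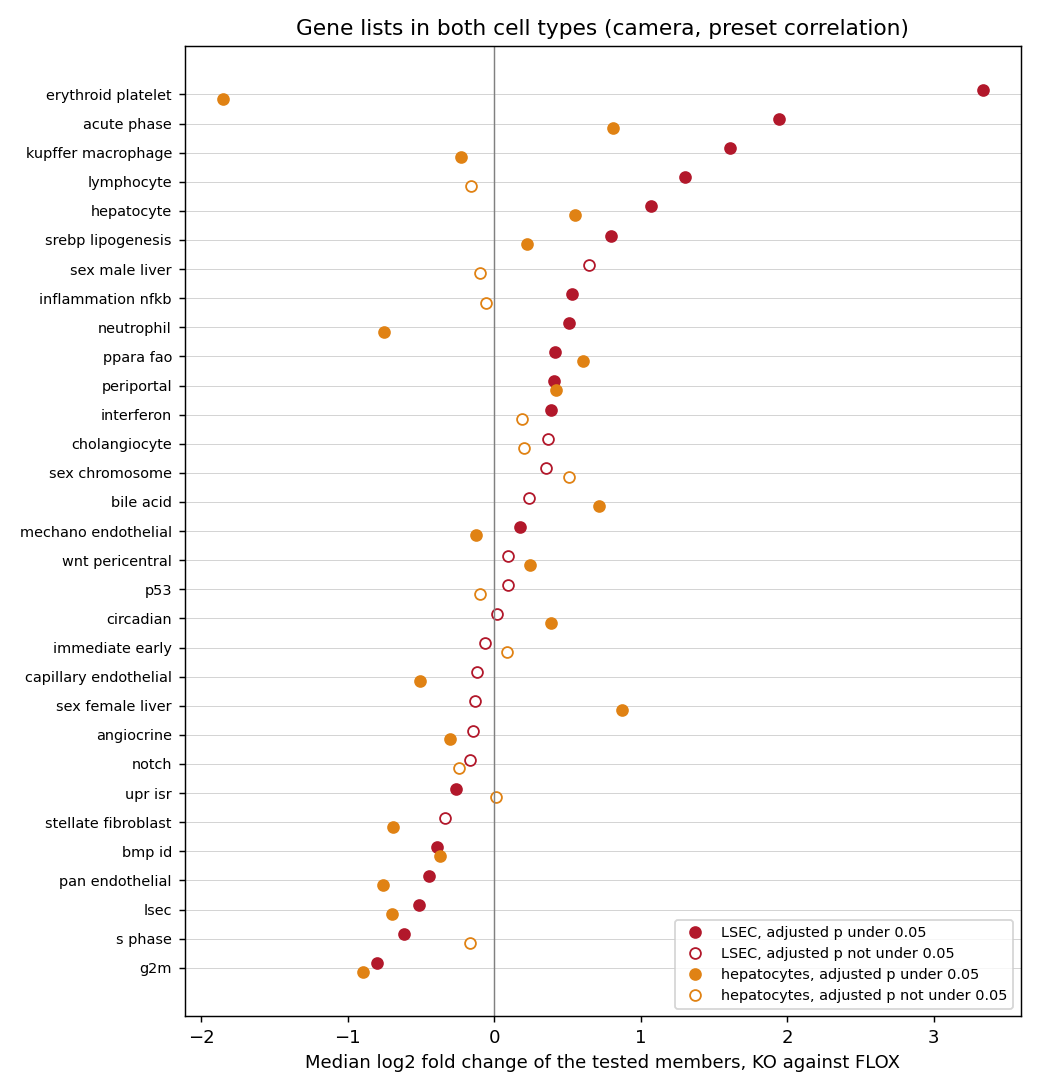
Median log2 fold change (KO against FLOX, horizontal axis) of the tested members of 31 gene lists in LSEC (red) and hepatocytes (orange), with filled points for lists that passed camera at the preset correlation. In LSEC the red cell and platelet list stands highest, at 3.33, and the mitosis list lowest, at -0.80.

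Over all genes, 4220 of 14660 changed in LSEC (limma adjusted p under 0.05), 2275 higher and 1945 lower in KO, and 1098 by a log2 fold change of at least 1. The KO and FLOX libraries did not overlap in 31.7% of the tested genes, where chance gives 2.86%. On the FPKM as deposited, whose median log2 fold change was -0.24, the split was 1596 higher and 4533 lower. In those values 7 flow-responsive genes were higher and 9 lower, as were 6 and 2 interferon genes, 12 and 6 NF-kB targets, 5 and 3 fatty acid oxidation genes, 4 and 2 periportal genes, and 1 and 9 stress-response genes. Without the genes that were higher on average in the hepatocyte libraries, 2440 of the changed genes were left, 1118 higher and 1322 lower. Of the 18 gene lists that passed camera, 12 kept their call with an estimated correlation. The authors' deposited table held 6737 genes past FDR 0.05, 3099 higher and 3638 lower in KO. Of 4219 genes that changed here and stand in it, 4026 passed there too, all with the same sign. Adjusted over the list alone, 18 LSEC identity genes, 18 general endothelial genes, 20 mitotic genes, 17 replication genes and 11 BMP and ID genes fell, and 15 lymphocyte, 16 lipid synthesis and 12 interferon genes rose. The other passing lists had the same counts as over all genes.

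In hepatocytes, KO libraries held more transcripts of several female-biased liver enzymes and of the pericentral Cyp1a2, and far fewer of pancreatic enzymes. The sulfotransferase gene Sult3a1 stood at 9.07 ± 1.23 FPKM in KO and 0.275 ± 0.0664 in FLOX (SD, n = 4), Cyp3a41b at 9.34 ± 1.12 against 1.12 ± 0.266, and Cyp1a2 at 380.2 ± 49.6 against 86.4 ± 4.70. Large rises were also those of Mup17 (10.2 ± 1.64 against 0.962 ± 0.437 FPKM), Mup19 (10.4 ± 2.61 against 1.43 ± 1.38), Uimc1 (50.4 ± 11.7 against 8.94 ± 2.65) and Gpcpd1 (329 ± 63.03 against 75.7 ± 18.97). The Mup and Cyp3a genes have near-identical copies among which fragments can be split, so single members are uncertain. The 8 largest falls were all digestive enzyme or other secretory genes of the exocrine pancreas: Ctrb1 (6.66 ± 0.947 against 1007 ± 161 FPKM), Prss2 (1.89 ± 0.260 against 314 ± 35.8), Try4 (2.40 ± 0.462 against 297 ± 39.6), Try5 (1.81 ± 0.703 against 234 ± 32.8), Cela2a (3.43 ± 2.18 against 350.0 ± 41.9), Cela3b (1.58 ± 0.450 against 201 ± 23.7), Reg2 (3.83 ± 2.08 against 364 ± 75.3) and Amy2a4, at 97.5 ± 15.6 in FLOX and listed at 0 in KO. Trypsin and amylase genes are near-identical copies too. All 23 pancreatic genes of a list added after the data were seen fell, with a median log2 fold change of -5.67, and summed to 4144 ± 422 FPKM in FLOX hepatocytes, 47.1 ± 4.62 in KO hepatocytes, 42.9 ± 5.60 in FLOX LSEC and 23.6 ± 6.51 in KO LSEC (SD, n = 4 each). The labels give no preparation day or batch, so tissue handling could not be separated from genotype for the pancreatic transcripts here or for the globin and mitochondrial transcripts in LSEC.

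Bile acid synthesis and transport genes rose in 16 of 17 cases in KO hepatocytes and 1 fell (camera adjusted p = 6.14e-11), with the uptake transporters Slco1b2 at 135 ± 3.65 against 46.8 ± 4.85 and Slc10a1 at 195 ± 12.8 against 78.99 ± 6.37 FPKM (SD, n = 4). Acute phase genes rose in 18 of 21 cases (camera adjusted p = 1.59e-13), with Itih4 at 2734 ± 119.7 against 1279 ± 60.1 and Itih3 at 1600.3 ± 72.5 against 798 ± 35.1, and 1 fell. Hepatocyte genes rose in 18 of 25 cases and 1 fell, with a median log2 fold change of 0.55 (camera adjusted p = 1.27e-11). Their leading members were Itih3 and G6pc, the glucose-6-phosphatase gene (2.30-fold). Fatty acid oxidation genes rose in 14 of 20 cases and 1 fell (camera adjusted p = 1.34e-07), including the fatty acid hydroxylase gene Cyp4a10 (2.54-fold). Periportal genes rose in 10 of 19 cases and fell in 4, with Cps1 up 1.61-fold and the gluconeogenic Pck1 up 1.73-fold (camera adjusted p = 0.00174). Female-biased liver genes rose in 9 of 11 cases and 1 fell, Sult3a1 among those that rose (camera adjusted p = 3.85e-08; adjusted p = 0.0545 with an estimated correlation). Of 7 male-biased genes, 3 rose and 3 fell (camera adjusted p = 0.981).

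Wnt target and pericentral genes rose in 8 of 22 cases and fell in 2 (camera adjusted p = 0.00115; adjusted p = 0.0789 with an estimated correlation). Their median log2 fold change was 0.25, against 0.55 for the hepatocyte list. Medians were 0.22 for sterol and fatty acid synthesis, 0.42 for periportal, 0.60 for fatty acid oxidation, 0.71 for bile acid and 0.81 for acute phase genes. A higher share of hepatocyte RNA in KO was not separated from changes of these lists. Cyp2e1, an ethanol-oxidising cytochrome, stood at 1576 ± 67.5 against 491 ± 38.4 FPKM. Clock genes rose in 8 of 15 cases and 1 fell, with Per2 up 2.24-fold and Tef up 2.13-fold (camera adjusted p = 0.00133; adjusted p = 0.0545 with an estimated correlation). Sterol and fatty acid synthesis genes rose in 7 of 20 cases, as Fasn (2.15-fold) and Insig1 (1.86-fold), and 1 fell (camera adjusted p = 0.00346; adjusted p = 0.0789 with an estimated correlation). Mitochondrially encoded genes held 10.8% ± 0.390 of the FPKM sum in KO hepatocytes and 14.7% ± 0.726 in FLOX hepatocytes (SD, n = 4; exact permutation p = 0.0286).

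**Figure D3:**
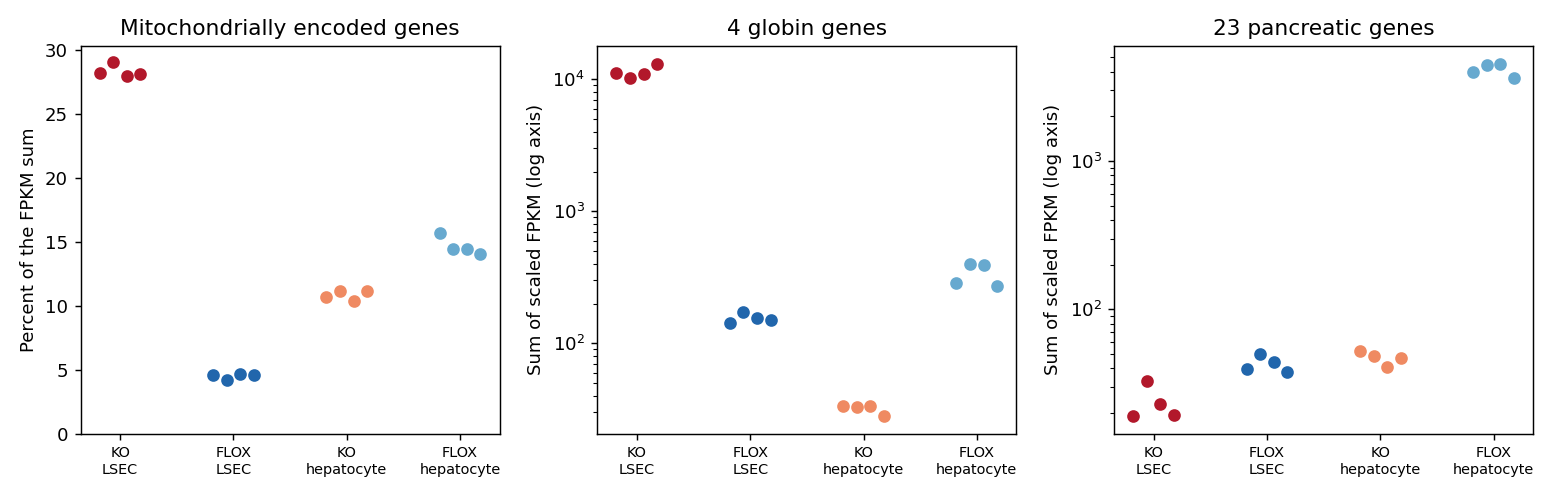
Mitochondrially encoded genes as percent of the FPKM sum (left), and summed scaled FPKM of 4 globin genes (centre) and 23 pancreatic genes (right, both on log axes), in each library of the 4 groups (points). The mitochondrial share lies between 28.0% and 29.1% in KO LSEC and between 4.18% and 4.71% in FLOX LSEC, and the pancreatic sum between 3633 and 4543 in FLOX hepatocytes.

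Mitotic genes fell in 20 of 28 cases in KO hepatocytes and none rose (camera adjusted p = 7.53e-12), with Cdc20 at 18.4 ± 1.77 against 50.9 ± 2.86 and the ubiquitin-conjugating enzyme gene Ube2c at 8.39 ± 0.960 against 24.6 ± 1.18 FPKM (SD, n = 4). General endothelial genes fell in 20 of 22 cases and none rose (camera adjusted p = 9.44e-13), among them Eng (55.3 ± 2.19 against 92.6 ± 3.19) and Ecscr (5.01 ± 0.354 against 12.6 ± 0.848). LSEC identity genes fell in 18 of 22 cases and 1 rose, with Clec4g at 171 ± 5.68 against 424 ± 46.2 and Ehd3 at 58.4 ± 1.65 against 103 ± 4.68 FPKM (camera adjusted p = 6.27e-09). Further lists of non-parenchymal cells were lower: 12 of 15 stellate cell genes fell, as Ecm1 and Lrat (1.63-fold and 2.61-fold; camera adjusted p = 6.99e-07; adjusted p = 0.0545 with an estimated correlation). Of 11 neutrophil genes 7 fell, as S100a8 and Retnlg (1.93-fold and 2.49-fold; 2.37e-05, with an estimated correlation adjusted p = 0.0545). Of 19 capillary genes 9 fell, as Sparc and Plvap (2.08-fold and 2.08-fold; 3.54e-05, with an estimated correlation adjusted p = 0.0545). Of 8 red cell and platelet genes 5 fell, as Hba-a2 and Hba-a1 (10.3-fold and 12.1-fold; 4.25e-05, with an estimated correlation adjusted p = 0.0825).

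Kupffer cell genes fell in 7 of 17 cases and rose in 2, with Clec4f at 384 ± 10.6 against 554 ± 65.8 and Marco at 460.1 ± 32.8 against 589 ± 26.7 FPKM (camera adjusted p = 0.0242; adjusted p = 0.283 with an estimated correlation). BMP and ID genes fell in 8 of 19 cases, led by Id1 and Eng, and rose in 2 (camera adjusted p = 0.000262; adjusted p = 0.0545 with an estimated correlation). Endothelial signals to hepatocytes fell in 9 of 24 cases, including Bmp2 (1.67-fold) and Igfbp7 (1.96-fold), and rose in 3 (camera adjusted p = 0.0247; adjusted p = 0.0789 with an estimated correlation). Flow-responsive genes fell in 8 of 21 cases, as Tek (1.76-fold) and Thbd (1.48-fold), and rose in 2 (camera adjusted p = 0.0279; adjusted p = 0.0789 with an estimated correlation). Median log2 fold changes were -0.37 for BMP and ID genes, -0.30 for endothelial signals (angiocrine genes) and -0.12 for flow-responsive genes. General endothelial genes fell further, with a median of -0.76. Less endothelial RNA in KO was therefore not separated from changes of these lists. DNA replication genes fell in 8 of 30 cases in hepatocytes, and the list did not pass (camera adjusted p = 0.0593). The angiocrine call was also lost without KO replicate 1 (camera adjusted p = 0.0577) and on the FPKM as deposited (0.0512), with a range over the alternatives of 7.36e-05 by fry to 0.929 by camera.

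Over all genes, 3539 of 13994 changed in hepatocytes (limma adjusted p under 0.05), 1773 higher and 1766 lower in KO, and 506 by a log2 fold change of at least 1. KO and FLOX libraries did not overlap in 29.1% of the tested genes, where chance gives 2.86%. On the FPKM as deposited, whose median log2 fold change was -0.16, the split was 1041 higher and 3335 lower. In those values 4 lipid synthesis genes were higher and 3 lower (6 and 2 with upper-quartile scaling), with a list median of 0.028, as were 6 and 2 clock genes, 2 and 12 angiocrine genes, 0 and 12 flow-responsive genes, and 0 and 10 Kupffer cell genes. Without the genes that were higher on average in the LSEC libraries, 2251 of the changed genes were left, 1446 higher and 805 lower. Of the 20 gene lists that passed camera, 8 kept their call with an estimated correlation, and another split of the same 8 libraries passed 21 lists. Adjusted over the list alone, 16 bile acid genes, 18 acute phase genes, 19 hepatocyte genes, 15 fatty acid oxidation genes, 10 female-biased genes, 10 clock genes, 9 Wnt target and pericentral genes and 8 lipid synthesis genes rose. 20 mitotic, 21 general endothelial, 18 LSEC identity, 12 capillary, 12 BMP and ID, 11 angiocrine, 9 flow-responsive, 9 Kupffer cell and 9 neutrophil genes fell.

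The difference between KO and FLOX libraries was not the same in the cell types, as for blood cell, macrophage and pancreatic transcripts. All 17 Kupffer cell genes had a higher log2 fold change in LSEC than in hepatocytes, with a median difference of 1.92 on the log2 scale (camera adjusted p = 2.23e-23). The same direction held for 9 of 10 red cell and platelet genes (median 3.51), 16 of 21 acute phase genes (1.17) and 15 of 22 NF-kB targets and chemokines (0.63). Bile acid genes went the other way, with 8 of 17 below in LSEC (median -0.49), as did 7 of 11 female-biased liver genes (-0.64). Only 13 of these bile acid genes and 6 of these female-biased genes were tested within LSEC. The median levels of these lists in FLOX LSEC were 1.60% and 1.66% of those in FLOX hepatocytes. On the log2(FPKM + 1) scale low values keep effects small, so these differences may mainly restate the hepatocyte change. Id1 fell less in LSEC than in hepatocytes (difference 0.79, limma adjusted p = 3.38e-05), whereas the difference for Wnt2 was 0.32 (adjusted p = 0.0772) and for Piezo1 0.27 (adjusted p = 0.317). In total the log2 fold change between KO and FLOX differed for 3200 of 15469 genes (limma adjusted p under 0.05), 2089 with a higher and 1111 with a lower effect in LSEC, and on the FPKM as deposited for 1814 and 1566.

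Genes that fell in both cell types numbered 623, where 234 would be expected of independent lists among 13279 genes tested in both. Those that rose in both numbered 489 (252 expected). A rise in LSEC with a fall in hepatocytes was found for 229 genes (266 expected), and the reverse for 108 (222 expected). Across these genes the correlation of the log2 fold changes was 0.17, and genes are not independent replicates.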

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

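The tests of explanations given below for Id1 and Wnt2, for hepatocyte transcripts in LSEC and for female-biased genes were chosen only after the results were seen, while the tests of single libraries and of the difference between cell types were fixed beforehand.

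Among named genes and cell type lists, 16 of 286 groups of 4 libraries held a library whose gap to the nearest of the others, divided by the range of the group, was above the 95% limit of Dixon's test. Chance gives about 14.3. Ifit1 in KO LSEC stood at 13.7 FPKM in replicate 1 and at 13.02 to 13.1 in the others, a ratio of 0.849. Selp in KO LSEC stood at 156 FPKM in replicate 2 and at 142 to 144 in the others, a ratio of 0.904. Lcn2 in KO LSEC stood at 586 FPKM in replicate 4 and at 501 to 514 in the others, a ratio of 0.846. Zfp46 in FLOX LSEC stood at 92.95 FPKM in replicate 2 and at 89.2 to 89.6 in the others, a ratio of 0.884. Immp2l in FLOX LSEC stood at 8.78 FPKM in replicate 4 and at 2.87 to 3.43 in the others, a ratio of 0.906. Cps1 in FLOX LSEC stood at 12.7 FPKM in replicate 1 and at 10.4 to 10.6 in the others, a ratio of 0.907. Cyp3a41b in KO hepatocytes stood at 7.67 FPKM in replicate 4 and at 9.77 to 9.999 in the others, a ratio of 0.902. Ctrb1 in KO hepatocytes stood at 8.07 FPKM in replicate 2 and at 6.06 to 6.34 in the others, a ratio of 0.863.

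Thbd in KO hepatocytes stood at 26.8 FPKM in replicate 1 and at 29.6 to 30.1 in the others, a ratio of 0.847. Sparc in KO hepatocytes stood at 126 FPKM in replicate 1 and at 131 to 132 in the others, a ratio of 0.844. Itih4 in KO hepatocytes stood at 2914 FPKM in replicate 1 and at 2673 to 2676 in the others, a ratio of 0.987. Kdm5d in KO hepatocytes stood at 2.75 FPKM in replicate 1 and at 1.23 to 1.33 in the others, a ratio of 0.931. Id1 in FLOX hepatocytes stood at 36.2 FPKM in replicate 4 and at 42.3 to 42.8 in the others, a ratio of 0.926. S100a8 in FLOX hepatocytes stood at 41.6 FPKM in replicate 4 and at 47.5 to 48.1 in the others, a ratio of 0.913. The mean log2 value of the lymphocyte list in FLOX LSEC stood at 1.98 in replicate 2 and at 1.65 to 1.69 in the others, a ratio of 0.881. The mean log2 value of the neutrophil list in KO hepatocytes stood at 2.54 in replicate 2 and at 2.27 to 2.32 in the others, a ratio of 0.831.

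The genotype effect differed between LSEC and hepatocytes, by the interaction term of limma, for 74 of 93 named genes, 53 with a higher and 21 with a lower effect in LSEC, and 24 had opposite signs. Most named genes were chosen for their change in these same data, which raises this share by construction. Over all genes 3200 of 15469 differed. Signs were counted whatever the size of the effect, as for Ankrd1 (1.85 in LSEC and -0.099 in hepatocytes). The tests of lists used camera on the same term, and 20 lists differed, 15 of them also with an estimated correlation. The calls lost with it were those of the hepatocyte, stellate cell and clock lists (adjusted p = 0.142 each), the general endothelial list (0.0885) and the Wnt target and pericentral list (0.0545). Differences are effects in LSEC minus effects in hepatocytes, on the log2 scale. In the globin and other blood cell genes the difference was 9.24 for Hba-a1, 9.56 for Hba-a2, 9.43 for Hbb-bs and 9.91 for Hbb-bt. It was 4.11 for Alas2, 3.35 for Ighm, 4.98 for Igkv6-23, 0.91 for Gzmb and -1.44 for Trbv14. In macrophage, neutrophil and inflammatory genes the difference was 1.91 for C1qc, 1.98 for Cd5l, 1.95 for Clec4f and 1.92 for Marco. It was 2.26 for Camp, 3.86 for Ngp, 1.53 for Retnlg and 1.45 for S100a8. Values also stood at 1.54 for Ccl3, 2.54 for Lcn2, 2.74 for Saa3 and 0.52 for Selp. The rest stood at 0.53 for Ifit1 and 0.97 for Oas2. In pancreatic genes the difference was 6.87 for Amy2a4, 6.47 for Cela2a, 5.35 for Cela3b and 5.79 for Ctrb1. It was 6.06 for Prss2, 6.005 for Reg2, 5.48 for Try4 and 5.95 for Try5. In hepatocyte, acute phase and lipid genes the difference was 1.55 for Fga, 1.43 for Fgg, 0.38 for Itih3 and 0.68 for Itih4. It was 0.71 for Pigr, -1.93 for Cps1, -0.96 for G6pc and -0.66 for Pck1. Values also stood at -0.75 for Slco1b2, 1.57 for Angptl4 and 0.65 for Fasn. In endothelial, BMP and stellate genes the difference was 0.27 for Bmp2, 0.79 for Id1, 0.58 for Clec4g and 0.77 for Ecscr. It was 0.29 for Eng, 0.66 for Igfbp7, 0.85 for Plvap and 0.63 for Sparc. Values also stood at 0.38 for Tek, 0.32 for Thbd, 1.96 for Ankrd1 and 1.97 for Hmox1. The rest stood at 1.01 for Ecm1 and -0.68 for Lrat. In female-biased, pericentral and clock genes the difference was -1.14 for Cyp1a2, -2.40 for Cyp3a41b and -3.16 for Sult3a1. It was -2.33 for Mup17, -2.45 for Mup19, -0.97 for Per2 and -0.89 for Tef. Cyp3a41b, Sult3a1, Mup17 and Mup19 were too low to be tested within LSEC. In cell cycle and stress response genes the difference was 0.49 for Cdc20, 1.18 for Ube2c, -1.31 for Dtl, -0.49 for Mcm5 and -0.66 for Pdia4. In the other named genes the difference was -1.66 for Get1, -1.41 for Gpcpd1, -1.75 for Immp2l and -2.35 for Uimc1. It was -0.95 for Zfp46 and 3.61 for mt-Nd6.

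By list, the median difference was 0.46 for the flow-response list, -0.013 for the Wnt target and pericentral list, -0.31 for the DNA replication list and 0.42 for the capillary list. It was 0.29 for the general endothelial list, 0.70 for the hepatocyte list, 1.92 for the Kupffer cell list and 1.41 for the lymphocyte list. Medians also stood at 1.36 for the neutrophil list, 0.46 for the stellate cell list, 3.51 for the red cell and platelet list and 0.51 for the interferon list. Further medians were 0.63 for the NF-kB list, 1.17 for the acute phase list, -0.49 for the bile acid list and 0.53 for the lipid synthesis list. The remaining ones were 0.37 for the p53 target list, -0.47 for the stress-response list, -0.37 for the clock list and -0.64 for the female-biased liver list.

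Id1 and Wnt2 were lower in KO LSEC, while general endothelial genes had a median log2 fold change of -0.45. A lower share of endothelial cells that raises every other cell type alike was argued against, because the macrophage list rose by 1.78 more than the stellate list, beyond 2 SD between libraries. RNA of other cells diluting the endothelial RNA stayed open in spite of the CD146 beads, with the macrophage gene Cd5l at 547 and Hba-a2 at 5040.0 FPKM in KO LSEC, since the lower of the pair, Wnt2, lay -0.680 SD of the general endothelial list from its median. Relative to the mean of that list, Wnt2 differed by -0.22 (exact permutation p = 0.0286, adjusted p = 0.0857) and Id1 by 0.060 (exact permutation p = 0.400). In hepatocytes Id1 lay -1.39 SD from the median (-0.38 relative to the list mean, exact permutation p = 0.0286, adjusted p = 0.0857, with 3 of 22 members lower), so a smaller endothelial share and a change within endothelial or other cells cannot be told apart there, and an effect of the deletion itself may contribute but was not separated from them.

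Hepatocyte transcripts were higher in KO LSEC, with a median of 2.63% of the KO hepatocyte level against 1.52% in FLOX. Carry-over of hepatocyte RNA at 1 share was argued against as the whole cause, because 6 of 25 list genes (among them Cps1, Cyp3a11, G6pc and Hpd) lay at 0.289% to 1.26%, while Alb lay at 2.57%. By the same measure 0 genes lay far below the median in FLOX, and the CD146 beads select against hepatocytes. Expression of acute phase genes in the LSEC fraction itself was also examined. Of 17 acute phase genes outside the hepatocyte list, 5 lay above every hepatocyte list gene in KO, as Saa3 at 145% and Steap4 at 65.4%. In FLOX 7 did, so this was not particular to KO. The measure gives a level, so it cannot decide whether such expression adds to the rise. Steap4 stood at 61.9% in FLOX, and Lbp at 39.4% in KO and 42.5% in FLOX. Saa3 stood at 21.3% in FLOX, Lcn2 at 23.1% in KO and 3.92% in FLOX, and Cp at 8.30% and 5.38%. RNA of macrophages and neutrophils, whose lists rose in KO LSEC, was not separated from these values. An effect of the genotype on the cells of the fraction was not tested separately.

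Female-biased liver genes were higher in KO hepatocytes, among them Sult3a1. More female animals behind these libraries was argued against only in part. The 4 Y-linked genes had a median log2 fold change of 0.54 (SD 0.30 between genes), above 0 in 4 of 4. Of them only Ddx3y passed (limma adjusted p = 0.000603). Xist, the RNA of the inactive X chromosome, was not lower in KO hepatocytes (log2 fold change 0.27, limma adjusted p = 0.546). It therefore gave no sign of fewer female animals. A higher share of hepatocyte RNA was argued against as the whole cause, because the log2 fold changes of the 11 female-biased genes lay farther from the median of both lists than those of the 25 hepatocyte genes, by 0.78 on average (two-sided permutation p = 0.00146 over genes, which are not independent). Of the 11, 4 lay above and 1 below every hepatocyte gene, and for the 6 within their range a higher share stayed open. Reads shared between Cyp3a and Sult copies, and a hormonal or genotype effect, could contribute and were not tested.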

How the results depend on the processing

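The FPKM as deposited, a pseudocount of 0.1 with the filter kept, and leaving out genes of the other fraction or mitochondrial, globin and pancreatic genes were alternatives chosen after seeing the data, and the others were planned. Under relative log expression and upper-quartile scaling, quality weights, no filter, a minimum of 1 FPKM and 1 fit over 16 libraries, where run, every gene count stayed within 1.5 times its value and all 53 genes per cell type taken by the naming rule other than Piezo1 kept their direction and call. The planned count-based alternative was not run because the files hold FPKM. At an adjusted p under 0.01 the counts were 2489 in LSEC, 1828 in hepatocytes and 1942 for the interaction. With a log2 fold change of at least 1 they were 1098, 506, 1186 and, between cell types, 5627. Fewer genes can pass these by construction. Without genes higher in the other fraction 2440 LSEC and 2251 hepatocyte genes were left. With fry 29 lists changed in LSEC, and with an estimated correlation 8 in hepatocytes. On the FPKM as deposited, where the missing scaling shifts the LSEC genes together (median -0.24), Piezo1 in LSEC passed at -0.53.

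With the list of the other cell type as a covariate, limma called 0 genes in LSEC (718 at an unadjusted p under 0.05) and 0 in hepatocytes (829), and camera 9 and 7 lists. Of the 53 genes per cell type other than Piezo1, 49 in LSEC and 43 in hepatocytes kept their direction and lost their call, and 3 and 10 reversed. The hepatocyte list separated KO from FLOX LSEC fully (mean log2 value 5.96 ± 0.05 and 5.01 ± 0.11, SD, n = 4). Covariate and genotype can hardly be told apart in such a fit, so precision is lost by construction. Over all alternatives, this fit included, log2 fold changes ran from 6.04 to 6.42 for Hbb-bs and 2.74 to 3.18 for Ngp in LSEC. They ran from -7.31 to -6.49 for Prss2 in hepatocytes, and more widely for Fga in LSEC (1.02 to 2.25). Several of the largest rises in LSEC also depended strongly on the processing. Their ranges were 1.73 to 7.08 for Mup9, 1.41 to 5.25 for Alas2, 1.53 to 5.25 for Igkv6-23 and 2.02 to 4.65 for mt-Nd6. With the covariate Piezo1 in hepatocytes stood at -1.88 (limma adjusted p = 0.831, range over the alternatives 0.00577 to 0.831). Signs were reversed for Get1 (1.86), Mest (0.55) and Zfp354a (1.08) and the test direction, not the median, of the periportal list (0.054) in LSEC. In hepatocytes they were reversed for Mup19 (-3.67), Gpcpd1 (-0.31), Atf2 (-0.63), Wnt2 (0.22), Igfbp7 (0.21), Tek (0.036), Clec4f (0.16), Marco (0.24), Per2 (-0.42) and Tef (-0.93), and for the Kupffer cell list (median 0.24). The test direction, not the median, reversed for the lists of neutrophils (-0.050) and clock genes (0.043). The medians of the capillary (0.23) and angiocrine lists (0.020) changed sign and their test direction did not.

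Leaving out 1 library at a time gave 3462 to 3773 genes in LSEC, 2705 to 3459 in hepatocytes, 2809 to 3204 for the interaction and 9345 to 9539 between cell types. Piezo1 ran from -0.34 to -0.22 in LSEC and from -0.61 to -0.43 in hepatocytes, and the lists from 16 to 18 and from 19 to 22. Of 424 and 412 such values of the 53 genes other than Piezo1, 423 and 412 kept direction and call, while Piezo1 in hepatocytes lost its call in 5 of 8 fits. Of 144 and 160 values of passing lists 138 and 159 kept theirs. Replicate numbers were not shown to pair the libraries: correlations of same-numbered libraries ran from -0.272 to 0.126, and not all were over 0.1. With the replicate block 3776, 2512, 2727 and 10056 genes and 16 and 21 lists were called, and Piezo1 in hepatocytes stood at -0.49 with a limma adjusted p of 0.0869. The block ended the calls of the flow-response (camera adjusted p = 0.0816) and stress-response lists (0.0527) in LSEC. With a pseudocount of 0.1 Trbv14 lost its call at -2.78, and the cause was not tested. Depth is known only as an estimate, so how far it limits genes at low FPKM was not tested.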

Other observations

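The Y-linked list and the sums of pancreatic and globin genes were examined only after the results were seen, and the splits of libraries were fixed beforehand.

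Several lists did not pass camera in LSEC. Of 26 angiocrine genes 4 rose and 8 fell (camera adjusted p = 0.234), of 15 stellate cell genes 5 rose and 9 fell (adjusted p = 0.160). Of 14 Notch pathway genes 1 rose and 5 fell (0.211). Capillary genes split into 4 up and 8 down of 21 (0.330). Immediate early genes, which respond within minutes to stimulation or tissue handling, split into 7 and 7 of 19 (0.807). Wnt target and pericentral genes split into 4 and 4 of 18 (0.863), p53 targets into 4 and 2 of 14 (0.691), and bile acid genes into 4 and 3 of 13 (0.314). Bile duct genes rose in 3 of 8 cases (0.0797). Clock genes rose in 2 and fell in 1 of 15 (0.691), and male-biased liver genes in 2 and 1 of 5 (0.224). Female-biased liver genes rose and fell in 1 and 2 of 6 (0.503), and sex chromosome genes in 2 and 1 of 5 (0.211).

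In hepatocytes, NF-kB targets and chemokines rose in 5 and fell in 6 of 22 cases (camera adjusted p = 0.568), and stress response genes in 6 and 4 of 19 (0.565). Interferon response genes rose in 1 and fell in 2 of 22 (0.603), immediate early genes in 2 and 4 of 19 (0.832), and p53 targets in 1 and 5 of 14 (0.0774). Notch pathway genes fell in 5 of 12 cases (0.0708) and lymphocyte genes in 2 of 13 (0.0593). Bile duct genes rose in 1 and fell in 2 of 7 (0.981), and sex chromosome genes rose in 1 of 5 (0.0729).

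Transcripts of both sexes were found together. Xist, the RNA of the inactive X chromosome, stood at 12.3 to 54.0 FPKM and the Y-linked Ddx3y at 3.86 to 12.3 FPKM, and Xist and the 4 Y-linked genes were above 0 in 16 of 16 libraries. No library therefore looked like RNA of a single animal, and pooling or mixing of material was not tested. Xist stood at 21.97 ± 8.09 against 41.3 ± 9.49 FPKM in KO and FLOX LSEC (limma adjusted p = 0.0335) and at 24.1 ± 5.06 against 20.9 ± 9.21 in hepatocytes (adjusted p = 0.546; SD, n = 4). Of the 4 Y-linked genes 2 rose in LSEC and 1 rose in hepatocytes. Ddx3y was higher in KO in both fractions (12.2 ± 0.984 against 5.92 ± 0.407 FPKM in LSEC, 8.65 ± 0.885 against 4.08 ± 0.465 in hepatocytes, SD, n = 4). The mix of sexes may therefore differ between KO and FLOX libraries, and its part in the genotype comparisons was not tested. Of 13 mitochondrially encoded genes 1 rose and 6 fell in hepatocytes, and of 14 tested pancreatic genes 1 rose and 7 fell in LSEC. The summed FPKM of the globin genes were 11413 ± 1231 in KO LSEC, 155 ± 13.7 in FLOX LSEC, 32.1 ± 2.68 in KO hepatocytes and 338 ± 67.2 in FLOX hepatocytes (SD, n = 4 each). The 10 genes with the highest FPKM held 32.0% of the sum in KO LSEC and 7.42% in FLOX LSEC.

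Splits of the libraries tested whether chance can account for the counts. In LSEC the real split, with 4220 genes, was the 1 split of 35 with as many, and the highest other gave 3. In hepatocytes the real split, with 3539 genes, was also the 1 of 35, and the highest other gave 2. Between the cell types in FLOX mice it was the 1 of 35 with 10188 genes, the highest other giving 0. For the genotype effect that differs between cell types it was the 1 of 100 drawn splits with 3200 genes, the highest other giving 1603. A chance assignment of these libraries was argued against for these 4 gene counts. Chance between animals or preparations could not be tested, because the libraries of a group may be technical. For the list counts chance was not excluded. The 18 lists in LSEC were reached by 1 of 35 splits, the smallest share possible, but the highest other called 16. The 20 lists of the interaction were reached by 2 of 100 (highest other 20), and the 20 lists in hepatocytes by 2 of 35 (highest other 21). Other splits often called many lists: 16 of 34 called at least 9 in LSEC, 15 of 34 at least 10 in hepatocytes, and 59 of 99 at least 10 for the interaction.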
